A study of Mus musculus with 2 samples.

How the data were processed

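Bone marrow cells of ICR mice aged 7 to 8 weeks were depleted of lineage-positive cells with magnetic beads and captured on the BD Rhapsody platform, per the labels' protocols. Cells came from 2 groups with 1 library each. The hypoxia group spent 13 days in an altitude chamber at 52.93 kPa, which the labels equate with 5000 m, with 19.5% oxygen, and the control group was killed on arrival. The control was therefore not kept in parallel for the same time, and differences between the libraries also hold time, age and handling. The number of mice behind each library is not given in the sources used here.

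The deposited values are raw counts of unique molecules (UMIs) per cell and gene after the pipeline's recursive substitution error correction, with no normalization. The tables were made with the BD WTA Rhapsody Analysis Pipeline 1.7.1 on GRCm38 with GENCODE vM19, per the file headers, and Bowtie2 is named in the submitters' processing notes. How cells were called before deposit is not given in the sources used here. The hypoxia table held 6406 cells and 137504361 UMIs, while 3956 cells and 121415081 UMIs were in that of the control. Gene columns numbered 26060 and 26039, of which 24393 were shared, and a gene missing from a table was taken as 0 there. At most 321 UMIs fell in any column found in 1 table alone.

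Cells with at least 500 UMIs and 200 detected genes and under 20% of UMIs from mitochondrial genes were kept. The first pair of limits removed no cell, since the deposited tables held none below them. Doublets were called per library with Scrublet in scanpy 1.11.5 (automatic threshold, seed 0), which marked 116 hypoxia cells (1.81%) and 36 control cells (0.91%). After both steps 6276 hypoxia and 3914 control cells remained. For clustering, counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were ranked within each library without mitochondrial, ribosomal protein, globin and sex-linked genes, and 30 principal components fed an exact 15-nearest-neighbour graph. Clusters came from the Leiden algorithm (leidenalg 0.10.2, resolution 1.0) on both libraries together, without integration. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0 and igraph 0.11.9, and R 4.3.3, were used.

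The deposited tables carry no cell annotation used here, so clusters were named from marker lists. A cluster took the name of the class with the most markers among its 30 leading genes (at least 3), and stayed unnamed where another class had more markers among its top 10. Leading genes were ranked by fold over the median of the other clusters. That contrast was chosen after the data were seen, among 3 that were tried. Ranking against all other cells left 3 of the clusters named erythroid progenitor here (2333 cells) and cluster 25 unnamed, and named cluster 4 erythroblast, cluster 11 HSC/MPP and cluster 28 T/NK/ILC. Ranking against the mean of the other clusters named cluster 14 erythroid progenitor and clusters 21 and 28 T/NK/ILC, and left clusters 6 and 11 unnamed. Of the clusters named monocyte here, it named cluster 8 (384 cells) plasmacytoid dendritic cell and left cluster 13 (320 cells) unnamed. Both dropped contrasts were kept as alternatives. No cluster took the plasma cell, macrophage, dendritic cell or stromal names. Class names end in "-like", and they were rebuilt here, so shares need not match any annotation by the authors.

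With 1 library per group there was no replicate, so no test was run and no p-value or standard error is given. Shares of cells have exact Clopper-Pearson 95% intervals. UMIs were summed over the cells of a class, scaled by the total of that class to CPM, and have exact Poisson 95% intervals, with exact intervals for ratios. All intervals cover counting error only, not differences between animals or preparations. Those of UMI sums treat each UMI as independent, so they also leave out variation between cells of a library. The log2 ratio of hypoxia over control was taken with 10 CPM added on both sides, so it understates the ratio of low genes. A count of 0 was read against a floor of 3 counts over the class. The log2 ratio and its interval were tested on Poisson counts simulated from the HSC/MPP-like sums (9673 genes), with 100 genes moved 2-fold and 100 moved 4-fold. These counts held no variation between cells, animals or preparations, so the test covers counting error only. The 95% interval held the true fold for 94% and 99% of them, and at the lowest for 90% (2-fold, whole library and monocyte-like cells). In HSC/MPP-like cells the direction was recovered for all 100 of each. The median log2 ratio recovered was 0.80 and 1.56, against 0.71 and 0.97 over the whole library, 0.74 and 1.41 in erythroid progenitor-like, 0.79 and 1.39 in granulocyte-monocyte progenitor-like and 0.76 and 1.48 in monocyte-like cells, with every direction recovered there too.

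Genes are named by a rule. Among genes with at least 50 UMIs over both libraries and at least 50 CPM in the higher library, the rule takes the 12 highest and 12 lowest log2 ratios in HSC/MPP-like cells. It takes 10 each in erythroid classes and over the whole library, 8 each in myeloid classes and 3 each in other classes. It adds the extreme members of gene lists and a fixed set of lineage regulators, and it leaves predicted genes, clones, mitochondrial and ribosomal protein genes out of the ranking. Genes outside the rule are said to be chosen after their values were seen. There were 30 gene lists. A list's value is the median log2 ratio of members with at least 20 UMIs, with its percentile among 10000 random lists of equal size matched on expression in 20 bins, as a description of these libraries. Members are counted as higher or lower at 1.5-fold, by size and not by test. Classes with under 30 cells in either library were left out of expression comparisons. Expression was compared in 11 named classes and over the whole library. Cluster 21 (44 and 45 cells) passed that limit but had no class name, so it is reported apart and counted in no statement over the 11 classes. Shares of cells with a UMI were taken after thinning each cell to 1000 UMIs, which left out no retained cell.

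Gene positions came from GENCODE vM21 on GRCm38, the same build as the files but a later annotation. It held 27499 of the 27706 gene columns by symbol. The H2 region was taken as chromosome 17 from 33974659 to 37483552, the span of the annotated H2 genes, and it held 192 gene columns.

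The marker lists, the rule for naming genes, the gene lists and 78 alternatives were fixed before the data were examined. The alternatives covered cell filters, doublets, clustering, class assignment, thinning, scaling with edgeR 4.0.16 TMM factors or DESeq2 1.42.0 size factors, the pseudocount (1 or 50 CPM) and the minimum of UMIs. A further 7 were chosen after the data were seen, namely 3 clusters left out in turn, H2-region members left out of lists, stress and H2-region genes left out of clustering, and the other naming contrasts. The DESeq2 factors came out as 1 in both libraries of the erythroid progenitor and T/NK/ILC-like classes, because low tied counts set the median. Under that setting the sums of these classes were therefore compared without scaling for depth. Figures were drawn with matplotlib 3.10.9.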

Results

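Single-cell transcriptomes of lineage-depleted bone marrow were compared between mice kept in a low-pressure altitude chamber for 13 days and control mice, to ask how blood stem and progenitor cells respond to hypoxia. Each group had 1 library. The retained cells numbered 6276 in the hypoxia library and 3914 in the control library, with median depths of 21345 and 32166 UMIs and 4938 and 5730 detected genes per cell. Values below are CPM within a class, hypoxia first, unless stated otherwise. Log2 ratios of genes near 0 in a library depend on the added 10 CPM, so both CPM values are given. H2-D1 lies on chromosome 17 from 35262730 to 35267499, Hsph1 on chromosome 5 from 149614287 to 149636376, Fos on chromosome 12 from 85473890 to 85477273 and Hsp90aa1 on chromosome 12 from 110690605 to 110702728 (GRCm38). No value has a replicate, and every interval covers counting error only. Transcripts of Y-linked genes were present in both libraries (Ddx3y at 120.0 against 98.3 CPM) while Xist had 28 and 17 UMIs in all.

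Erythroid progenitor-like cells were the largest class in both libraries, with monocyte-like cells holding a larger share, and megakaryocyte-like and HSC/MPP-like cells smaller shares, of the hypoxia library. Monocyte-like cells made up 14.1% of hypoxia cells (95% interval 13.3 to 15.02) and 5.19% of control cells (4.51 to 5.93), a ratio of 2.72 (2.34 to 3.19). Clusters 8 and 12 of that class were also led by Mpo and Prtn3, used here as markers of granulocyte-monocyte progenitors. Megakaryocyte-like cells made up 1.27% and 3.45%, a ratio of 0.370 (0.277 to 0.491). HSC/MPP-like cells were a cluster led by Cd34, Hlf and Flt3 but also by Mpo, Prtn3, Ctsg and Dntt. Its top 10 genes held 3 markers of its own class and 3 of granulocyte-monocyte progenitors. HSC/MPP-like cells made up 4.51% and 6.52%, a ratio of 0.692 (0.582 to 0.823). With each library clustered alone, 289 hypoxia cells and 0 control cells took that name, so this ratio has no value there. Basophil/mast-like cells (10.7% and 8.00%, ratio 1.33) and eosinophil-like cells (1.12% and 0.537%, ratio 2.08) were also more frequent in the hypoxia library. The ratio was 1.002 for granulocyte-monocyte progenitor-like, 1.07 for neutrophil-like, 0.849 for lymphoid-primed progenitor-like, 0.935 for B-lineage-like and 0.673 for T/NK/ILC-like cells, and each of those intervals included 1. The T/NK/ILC-like ratio was 1.59 with each library clustered alone. Endothelial-like cells were 0 of 6276 hypoxia cells, which allows a share of up to 0.0478% as 3 counts of the total (0.0588% as the Clopper-Pearson limit), and 10 of 3914 control cells.

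Other shares depended on how cells were assigned. Erythroid progenitor-like cells made up 48.8% and 56.3% of cells (ratio 0.868), but the ratio was 1.04 over progenitor classes alone and 1.24 with clusters named against all other cells. Megakaryocyte-erythroid progenitor-like cells made up 2.21% and 5.65% (ratio 0.392), a class that was not named under most other clusterings. Erythroblast-like cells made up 4.54% and 0.894% (ratio 5.08), but the ratio was 0.847 with each library clustered alone, 0.702 in thinned cells, 0.624 with clusters named against the mean of the others (8 cells in each library), 1.98 without the cell filter and 2.31 with a marker score per cell. The monocyte-like ratio stayed above 1 under every alternative run, between 1.87 and 6.12 (the latter in thinned cells), and was 2.24 with stress and H2-region genes left out of clustering. The megakaryocyte-like ratio stayed below 1 under every alternative run, between 0.306 and 0.397. Bead depletion of mature cells can set the shares of mature classes, and the gap in depth can affect clustering.

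**Figure D1:**
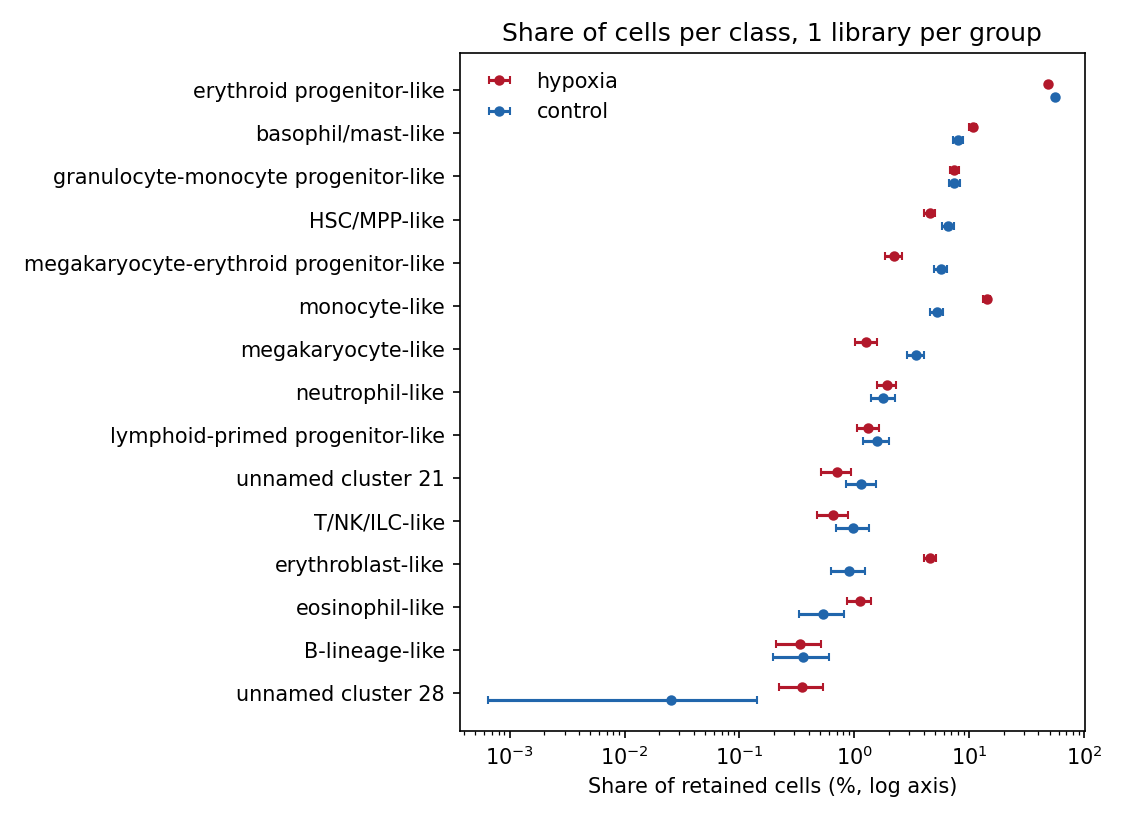
Share of retained cells in each class (%, log axis) in the hypoxia (red) and control (blue) libraries, with points for the share and bars for exact Clopper-Pearson 95% intervals. Monocyte-like cells lie at 14.1% and 5.19%, and megakaryocyte-like cells at 1.27% and 3.45%.

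In HSC/MPP-like cells (283 and 255) H2-D1 and other class I genes of the H2 region were higher in the hypoxia library, while Fos and most other immediate early and dissociation stress genes were lower. H2-D1, a classical class I heavy chain, was at 1816 against 478 CPM, a ratio of 3.79 (3.61 to 3.99). Fos, a subunit of the AP-1 transcription factor, was at 274 against 902 CPM, a ratio of 0.304 (0.282 to 0.327). Genes that respond directly to hypoxia-inducible factor had a median log2 ratio of 0.0066, and markers of stem cell identity 0.021. The cluster was led by stem cell, lymphoid and granulocyte-monocyte progenitor markers. Whether the mix of such cells differed between the libraries was not tested.

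The highest log2 ratios in this class were those of H2-Q6 (99.8 against 1.698 CPM, log2 3.23) and H2-Q7 (94.5 against 1.94 CPM, log2 3.13), class I genes whose near-identical sequences make the split of reads between them uncertain. Coro2a, an actin-binding coronin, followed at 217 against 17.2 CPM with a ratio of 12.6 (9.88 to 16.3). Ms4a6c, a membrane protein of myeloid cells, was at 66.6 against 7.04 CPM, Gdpd3, a lysophospholipase D, at 107 against 17.2 CPM, and H2-Q4 at 189 against 77.6 CPM. Begain was at 80.9 against 26.4 CPM, the erythroid carbonic anhydrase Car1 at 57.5 against 19.4 CPM, and the adhesion receptor Adgrg7 at 58.6 against 20.4 CPM. The log2 ratio of Car1 was 1.20, but -0.24 with the stricter cell filter. The basophil and mast cell proteases Prss34 (92.1 against 4.37 CPM) and Cpa3 (275 against 78.8 CPM) were also among the highest. Of the Prss34 UMIs in hypoxia cells, 49.2% came from 1 cell, and the log2 ratio was 2.07 without the top cell of each library, against 2.83 with it.

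The lowest log2 ratios in the class began with Cxcl12, a stromal chemokine, with 0 UMIs in the hypoxia cells and 292 CPM in the control cells, at least 328-fold higher in control, but from 7 control cells, 1 of which held 38.9% of the UMIs. Msh5, a meiotic DNA repair factor, was at 2.96 against 72.5 CPM, the splicing factor Cwc22 at 55.4 against 311 CPM, and the large heat-shock chaperone Hsph1 at 70.2 against 303 CPM, a ratio of 0.232 (0.201 to 0.267). The AP-1 genes Fosb (40.9 against 155 CPM) and Junb (64.9 against 162 CPM) lay in this group with Fos. So did the chemokine Ccl4 (132 against 453 CPM), the G-protein regulator Rgs1 (145 against 382 CPM), the glyoxalase Glo1 (56.6 against 158 CPM), the cytokine gene Osm (23.1 against 66.7 CPM) and the coagulation factor F13a1 (24.0 against 68.4 CPM). F13a1 had a log2 ratio of -1.21, but 0.52 when cells were assigned by marker score.

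Among the fixed regulators, the receptor gene Flt3 was at 254 against 161 CPM in HSC/MPP-like cells (ratio 1.58, 1.42 to 1.75), and Cd34, a progenitor surface marker, at 911 against 743 CPM. The myeloid regulator Cebpa was at 162 against 239 CPM (ratio 0.679, 0.611 to 0.755) and the proliferation marker Mki67 at 254 against 379 CPM (ratio 0.671, 0.617 to 0.730). Kit was at 384 against 318 CPM, with a log2 ratio of 0.26 but -0.067 under assignment by marker score. Hlf, a stem cell transcription factor, was at 385 against 349.6 CPM, with a log2 ratio of 0.14 but -0.018 when each cell counted alike. Under assignment by marker score the log2 ratio of Cebpa was -0.12 (from -0.53), that of Mki67 -0.88 (from -0.56) and that of Cpa3 0.87 (from 1.68), and with the stricter cell filter that of Flt3 was 0.39 (from 0.62). The intervals of the ratio included 1 for Mecom (23.1 against 18.0 CPM), Procr (17.8 against 22.8 CPM), Spi1 (63.4 against 65.3 CPM), Gata1 (14.2 against 11.6 CPM), Gata2 (188 against 204 CPM) and Hif1a (43.2 against 45.1 CPM).

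Of 26 measured immediate early and dissociation stress genes, 18 were at least 1.5-fold lower in hypoxia HSC/MPP-like cells, 0 higher and 8 between, with a median log2 ratio of -0.80 at the percentile 0 of random lists. Of 17 genes of MHC class I and antigen processing, 7 were higher and 0 lower, with a median of 0.53 (percentile 100). Without members inside the H2 region of chromosome 17 that median was 0.10. Of 34 interferon response genes 8 were higher and 0 lower, led by Phf11b (24.3 against 4.12 CPM) and Iigp1 (14.5 against 3.15 CPM), with a median of 0.31 (percentile 100). Of 53 G2/M genes 4 were lower, including Cenpf (99.8 against 191 CPM) and Birc5 (116 against 189.7 CPM), and 0 higher, with a median of -0.34 (percentile 0), whereas the 42 S phase genes had a median of 0.056. The unfolded protein and integrated stress response list had 7 of 23 members lower, including Sdf2l1 (52.4 against 116 CPM) and Atf3 (0 against 7.04 CPM), and a median of -0.27 (percentile 0).

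Medians of the other lists in HSC/MPP-like cells were smaller in size or rested on few genes. They were 0.44 for MHC class II (3 of 7 members higher, led by Cd74 at 7.40 against 0 CPM and H2-Aa at 11.8 against 2.67 CPM), 0.25 for mitochondrially encoded genes, 0.19 for cholesterol synthesis and 0.15 for cytokine and niche receptors. The lymphoid regulators had 0.16, or -0.061 with the stricter cell filter, with 4 of 14 members higher, led by Dntt (239.9 against 112 CPM) and Ets1 (43.5 against 20.6 CPM). The erythropoietin and STAT5 response had -0.24, p53 targets -0.16, ribosomal proteins -0.12, granule proteins -0.11, myeloid regulators -0.11, quiescence genes -0.10, nuclear oxidative phosphorylation -0.10, and the NF-kB and inflammatory list -0.072. The medians were 0.0059 for glycolysis (19 of 19 members between), 0.073 for the TCA cycle, 0.084 for iron handling, 0.011 for haem synthesis, 0.070 for autophagy and mitophagy, 0.011 for antioxidant genes and 0.0043 for erythroid and megakaryocytic regulators. The sex-linked transcripts had 4 measured members with a median of 0.33, and the globins 3 with a median of 1.47. Of the 27 measured HIF target genes 26 lay between, 1 was higher and 0 lower, led by Pdk1 (73.7 against 36.9 CPM) and Bnip3 (35.2 against 22.6 CPM). Assignment by marker score turned the medians of granule proteins (0.38), myeloid regulators (0.091) and the NF-kB list (0.091), and the mean of per-cell CPM turned that of stem cell identity (-0.16).

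**Figure D2:**
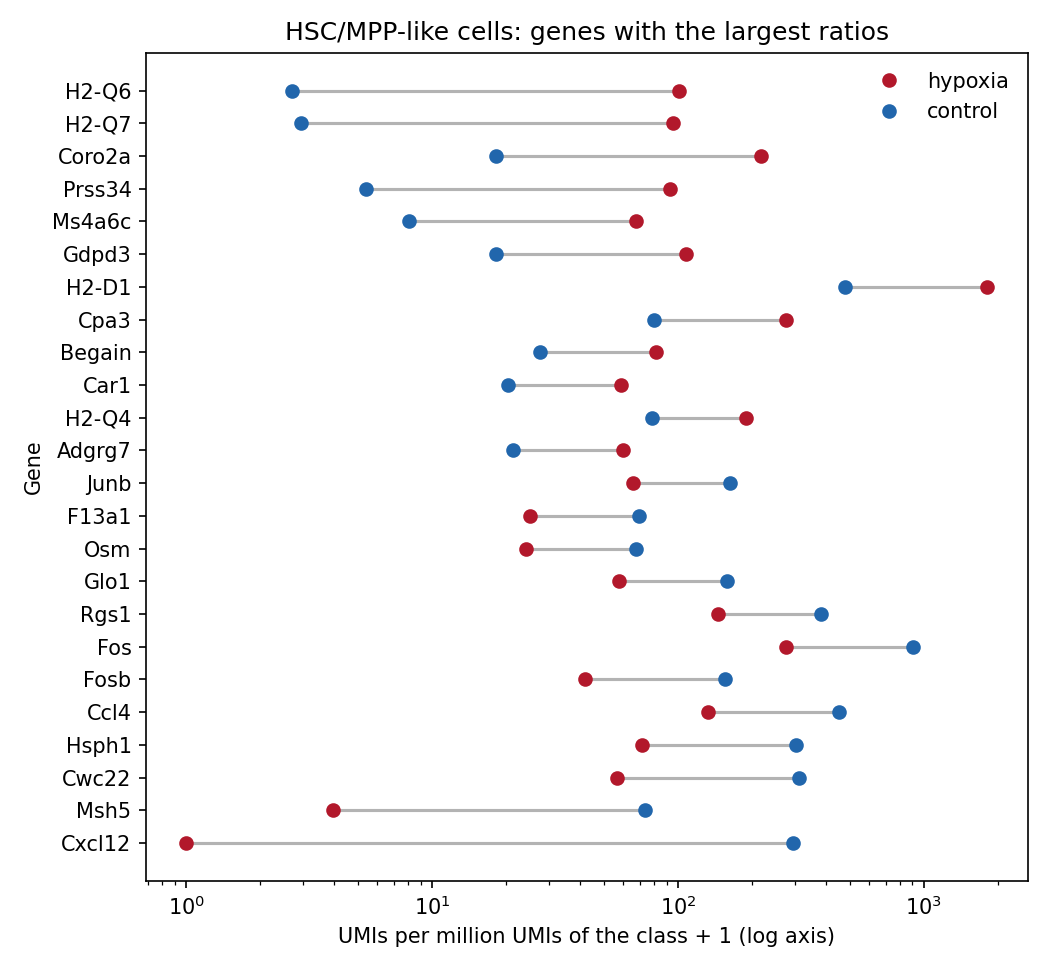
CPM in HSC/MPP-like cells plus 1 (log axis) of the 12 genes with the highest and the 12 with the lowest log2 ratio, hypoxia library in red and control library in blue, 1 point per library. H2-Q6 lies at 99.8 and 1.698 CPM, and Hsph1 at 70.2 and 303 CPM.

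In thinned HSC/MPP-like cells, a Flt3 UMI was found in 23.3% of hypoxia (18.5 to 28.7) and 14.1% of control cells (10.1 to 19.0), and in 0 of 3065 and 0 of 2202 erythroid progenitor-like cells. Without thinning the shares were 74.2% and 65.1%, beside 1.53% and 0.863% of erythroid progenitor-like cells. Median depths before thinning were 11083 and 15395 UMIs in HSC/MPP-like cells and 27944 and 41363 in erythroid progenitor-like cells. Hlf was found in 32.2% and 26.7% of thinned HSC/MPP-like cells (77.0% and 78.8% unthinned), beside 0.131% and 0.363% of erythroid progenitor-like cells (2.19% and 6.36% unthinned). Cd34 was found in 51.9% and 46.7% (95.1% and 92.2% unthinned), beside 0.163% and 0.0454% of erythroid progenitor-like cells (3.62% and 2.54% unthinned). Prss34 and Hba-a1, genes of basophils and red cells, were also found outside those classes, in a larger share of hypoxia than of control cells, and the source of these UMIs was not tested. Thinned Prss34 shares were 3.89% and 0.784% in HSC/MPP-like and 2.64% and 0.318% in erythroid progenitor-like cells, beside 78.2% and 60.1% of basophil/mast-like cells. Thinned Hba-a1 shares in HSC/MPP-like cells were 4.95% and 0%.

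Erythroid progenitor-like cells (3065 and 2202) in the hypoxia library had more H2-D1 and Tspo2 and less of the chaperones Hsp90aa1 and Hsph1. Hsp90aa1, a cytosolic heat-shock chaperone, was at 2176 against 5112 CPM, a ratio of 0.426 (0.423 to 0.428), and Hsph1 at 214 against 997 CPM, a ratio of 0.215 (0.211 to 0.218). Tspo2, a transporter of erythroid cells, was at 196 against 42.5 CPM, a ratio of 4.62 (4.46 to 4.78). The class was spread differently over its clusters in each library. Its largest clusters in the hypoxia library were 2 (805 cells), 1 (724), 0 (701) and 4 (535), and in control 3 (749 cells, against 27 in hypoxia), 0 (538) and 1 (303).

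Hba-a2, an alpha-globin, was at 83.6 against 4.95 CPM in erythroid progenitor-like cells, Hbb-bs, a beta-globin, at 535 against 174 CPM, and Slc4a1, the anion exchanger of red cells, at 112 against 32.5 CPM. Their log2 ratios of 2.65, 1.57 and 1.52 were 1.60, 1.02 and 0.33 without cluster 4 and 1.52, 0.91 and 0.26 with doublets kept. Globins were also higher outside the erythroid classes, with a median above 0 in every named class with a measured member except erythroblast-like cells (9 of 10, erythroid progenitor-like cells included), 1.47 in HSC/MPP-like and 1.54 in megakaryocyte-like cells, and Hba-a1 at 28.02 against 3.77 CPM in monocyte-like cells. In thinned cells an Hba-a1 UMI was found in 30.2% and 16.03% of erythroid progenitor-like cells (76.8% and 61.7% unthinned), beside 4.03% and 1.92% of basophil/mast-like cells (24.6% and 7.99% unthinned). How much of the erythroid difference came from RNA of other cells was not tested. The leading genes of cluster 4 held 5 erythroblast and 5 erythroid progenitor markers. H2-D1 was at 901 against 209 CPM, the glutathione transferase Gstp3 at 86.9 against 28.6 CPM, Cpne2 at 237 against 91.5 CPM, the ubiquitin ligase Dtx3 at 153 against 59.1 CPM, the sialic acid enzyme Cmas at 82.0 against 29.05 CPM and the LIM protein Csrp1 at 87.6 against 31.6 CPM. Lower in hypoxia were the D-type cyclin Ccnd2 (39.8 against 189.8 CPM), Cwc22 (60.2 against 208 CPM), the chaperone partners Chordc1 (129 against 360.4 CPM) and Dnaja1 (325 against 855 CPM), Asb17 (19.1 against 64.7 CPM), the immediate early gene Ier2 (30.8 against 86.1 CPM), the kinase Pim1 (44.1 against 116 CPM) and Glo1 (116 against 275 CPM). The erythroid regulators Gata1 (391 against 289.7 CPM), Klf1 (250.3 against 272 CPM) and Epor (172 against 135 CPM) had log2 ratios of 0.42, -0.12 and 0.33. Kit was at 224 against 172 CPM and Mki67 at 685 against 546 CPM, with a log2 ratio of 0.32, or 0.14 without cluster 4.

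In the same class the immediate early and dissociation stress list had 11 of 25 members lower, 0 higher and a median of -0.40 (percentile 0). The class I list had 9 of 17 higher and a median of 0.66 (percentile 100), or 0.14 without the H2 region. Of 15 haem synthesis genes 4 were higher, led by Tspo2 and Alas2 (23.8 against 10.7 CPM), and the median was 0.36 (percentile 99.99), or 0.15 without cluster 4 and 0.15 with doublets kept. The globins had a median of 0.70 (3 of 6 higher, or 0.12 with no minimum of UMIs), and autophagy and mitophagy 0.21 (3 of 22 higher, led by Map1lc3a at 21.6 against 10.1 CPM and Bnip3l at 235 against 149.8 CPM). HIF targets had a median of -0.049 with 1 of 30 higher and 5 lower, glycolysis -0.16, and the erythropoietin and STAT5 response -0.13, where Ccnd2 and Pim1 were lowest. The unfolded protein list had 8 of 25 members lower and a median of -0.28. The S phase and G2/M medians were 0.18 and 0.13, or 0.069 and 0.0070 with TMM factors. Of 37 interferon response genes 4 were higher, with a median of 0.26.

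Erythroblast-like cells (285 and 35) rested on few control cells, and the median log2 ratio of all their measured genes was 0.20, so values here are read against that shift. Class I transcripts were higher in the hypoxia library and beta-globin Hbb-bt was lower. H2-D1 was at 674 against 65.4 CPM (ratio 10.3, 7.11 to 15.5), H2-K1 at 154 against 25.7 CPM and Tspo2 at 226 against 44.4 CPM. Apol11b was at 94.5 CPM with 0 control UMIs, at least 13.5-fold higher. The linker histone H1f0 (94.3 against 11.7 CPM), Rhobtb3 (57.5 against 7.01 CPM), Zmiz1 (65.6 against 9.35 CPM), Usf3 (68.3 against 11.7 CPM), Vamp2 (58.7 against 9.35 CPM) and Tac2 (157 against 37.4 CPM) were the other highest genes, with control UMIs in 2 to 7 cells each. The lowest were Xpo7, Rsad2, Hbb-bt (4858 against 25519.7 CPM), the survival gene Bcl2l1, Irgm2, Tent5c, Gda, Tcp11l2, Tmcc2 and Cdkn2d (46.6 against 236 CPM). Cluster 29, a small group with 8 cells in each library, was 8 of the 35 control cells. Without it the log2 ratio of Xpo7 was 0.21 against -3.10 with it, that of Rsad2 -1.08 against -2.62, Bcl2l1 -1.05 against -2.32, Irgm2 -1.66 against -2.32, Tent5c -0.97 against -2.25, Gda -1.47 against -2.19, Tcp11l2 -0.40 against -2.15, and Tmcc2 -0.53 against -2.13. Under assignment by marker score the log2 ratio of Hbb-bt was -0.80 against -2.39, that of Cdkn2d -0.20 against -2.12, and that of H2-K1 1.06 against 2.20. The class I list had a median of 0.96 (7 of 12 members higher), or 0.39 without the H2 region and 0.35 under assignment by marker score. The globins had -1.51, or 0.30 when cells were assigned by marker score, and the immediate early list -0.20, with a counting interval that included 0.

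Granulocyte-monocyte progenitor-like cells (466 and 290) had the class I and stress differences seen in the other classes, and less S100a8 and S100a9, mostly through cluster 25. S100a9, an abundant neutrophil protein, was at 64.0 against 263 CPM (ratio 0.243, 0.224 to 0.265), S100a8 at 93.5 against 254 CPM and Wfdc21 at 34.4 against 102 CPM. S100a9 UMIs were in 39 hypoxia and 50 control cells, with 29.7% and 17.9% of them in 1 cell each. Without cluster 25 (19 and 22 cells), a choice made after the data were seen, the log2 ratio of S100a9 was -0.33 (from -1.88), that of S100a8 -0.29 (from -1.35) and that of Wfdc21 -1.25 (from -1.34). With the stricter cell filter they were -2.65, -2.01 and -1.59. The granule protein list had 2 of 14 members lower and 1 higher, with a median of -0.087 whose counting interval included 0. Ms4a6c was at 133 against 22.9 CPM (ratio 5.8, 5.01 to 6.74), H2-D1 at 1379 against 388 CPM, H2-Q7 at 54.0 against 0.665 CPM and H2-Q4 at 88.5 against 38.1 CPM. The immunoglobulin gene Ighm (80.4 against 20.9 CPM), Gdpd3 (62.8 against 16.0 CPM), the chemokine Ccl9 (581 against 240.3 CPM) and the granule release factor Unc13d (75.7 against 30.3 CPM) were also among the highest. The muscle creatine kinase Ckm (4.57 against 61.2 CPM), Cwc22 (44.0 against 211 CPM), Hsph1 (80.9 against 238 CPM), Ccl4 (21.9 against 67.7 CPM) and Mgst2 (23.4 against 61.3 CPM) were among the lowest. Cebpa was at 239 against 305 CPM and Spi1 at 96.8 against 103 CPM. The immediate early list had 12 of 25 members lower with a median of -0.57 (percentile 0). The class I list had a median of 0.47 (percentile 100), but -0.0034 without the H2 region.

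Monocyte-like cells (887 and 203) in the hypoxia library had more Ly6c1, Ms4a4c and H2-D1 and less Ccl4 and Fosb. They came mainly from clusters 13 (298 hypoxia, 22 control cells), 12 (292 and 41) and 8 (257 and 127). The class therefore mixed its clusters differently in each library. How much of the differences below came from that mix was not tested. H2-D1 was at 1648 against 386 CPM (ratio 4.27, 4.06 to 4.49), Ly6c1 at 60.5 against 3.54 CPM, Ms4a4c at 50.2 against 0.236 CPM with 1 control UMI (ratio 213, 38.1 to 8429.9), Coro2a at 135 against 16.3 CPM, Prss34 at 59.1 against 8.48 CPM, Cd7 at 72.2 against 15.6 CPM, the semaphorin Sema4a at 88.6 against 22.2 CPM and the lysosomal sulfatase Arsb at 186 against 55.4 CPM. Ccl4 was at 63.8 against 369.8 CPM (ratio 0.172, 0.159 to 0.187), Fosb at 37.2 against 166 CPM, Rgs1 at 7.71 against 51.6 CPM, the chromatin factor Hmga2 at 17.8 against 91.7 CPM, Hsph1 at 68.0 against 295 CPM, Cwc22 at 44.7 against 231 CPM and Msh5 at 3.72 against 59.9 CPM. Vcam1 was at 4.44 against 55.4 CPM, with 86.8% of its hypoxia UMIs in 1 cell, and its log2 ratio of -2.18 was 0.049 under assignment by marker score. Flt3 was at 136 against 210.0 CPM and Spi1 at 144 against 109.8 CPM. The immediate early list had 21 of 27 members lower and 1 higher, with a median of -0.98. The class I list had 8 of 17 higher, with a median of 0.44, or 0.24 without the H2 region.

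Neutrophil-like cells (120 and 70, with median depths of 2835 and 3875 UMIs) had a median log2 ratio of all measured genes of 0.13. Gdpd3 was at 351 against 31.7 CPM (ratio 11.1, 5.85 to 23.5), while the class I gene H2-Q10 had 0 UMIs in hypoxia and 336 CPM in control, at least 48.2-fold higher there. Fmo5 (102 against 19.02 CPM), Tinagl1 (146 against 34.9 CPM), Ly6e (376 against 130.0 CPM), Alcam (114 against 34.9 CPM), Setd2 (165 against 53.9 CPM) and Sema4d (232 against 82.4 CPM) were among the highest. Wfdc17 (41.8 against 317 CPM), Rdh12 (41.8 against 206 CPM), Chil5 (32.5 against 165 CPM), Wfdc21 (2065 against 6597 CPM), Nusap1 (44.1 against 111 CPM) and Osm (239 against 542 CPM) were among the lowest. The near-identical stefins Stfa3 (highest group) and Stfa2 (lowest group) had 50.6% and 54.1% of their hypoxia UMIs in 1 cell, and reads may be split between them. The immediate early list had a median of -0.38, or -0.22 under assignment by marker score, and the class I list 0.46, or 0.093 without the H2 region.

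The other 5 named classes also had an immediate early median below 0 and a class I median above 0. The immediate early median was -1.53 in megakaryocyte-erythroid progenitor-like, -1.17 in lymphoid-primed progenitor-like, -1.02 in megakaryocyte-like, -0.81 in T/NK/ILC-like and -0.64 in basophil/mast-like cells, and the class I medians were 0.47, 0.47, 0.45, 0.31 and 0.35. Without the H2 region the class I medians were, in the same order, -0.027, 0.15, 0.22, 0.10 and 0.19. With all members, that of T/NK/ILC-like cells was 0.14 with median-of-ratios factors (which left the sums of this class unscaled) and 0.10 with doublets kept, that of lymphoid-primed progenitor-like cells was 0.22 with a minimum of 100 UMIs, and the immediate early value of the latter class was -0.78 under assignment by marker score. In megakaryocyte-erythroid progenitor-like cells Tspo2 (197 against 1.20 CPM), H2-Q7 (0 control UMIs, at least 73.2-fold higher) and BC051537 (144 against 7.19 CPM) were highest and Msh5 (2.66 against 115 CPM), Fos (43.9 against 336 CPM) and Hsph1 (77.1 against 519 CPM) lowest, and their glycolysis median was -0.39. In megakaryocyte-like cells H2-Q7 (85.5 against 0.313 CPM), Mpo (109 against 7.83 CPM, with 46.4% of its hypoxia UMIs in 1 cell) and Prss34 (68.5 against 3.13 CPM) were highest, and Fos (18.2 against 261 CPM), Fosb (14.6 against 179 CPM) and the inducible chaperone Hspa1b (0 hypoxia UMIs, at least 67.8-fold higher in control) lowest. In lymphoid-primed progenitor-like cells Coro2a (223 against 1.33 CPM), H2-Q7 (0 control UMIs, at least 26.6-fold higher) and H2-Q6 (92.5 against 1.33 CPM) were highest and Fosb (13.2 against 225 CPM), Fos (201 against 1500.4 CPM) and Cwc22 (43.2 against 357 CPM) lowest. In T/NK/ILC-like cells (41 and 38) H2-Q7 (0 control UMIs, at least 23.6-fold higher), Ms4a4b (543 against 5.25 CPM) and Ly6a (1075 against 42.0 CPM) were highest. Cwc22 (41.3 against 273 CPM) was among the lowest, with Mcpt8 and Prss34, whose control UMIs came almost wholly from 1 cell (100% and 99.3%). In basophil/mast-like cells the eosinophil ribonuclease genes Ear1 (625 against 6.07 CPM) and Ear10 (0.341 against 82.4 CPM), near-identical paralogs whose reads the counting could split, lay at opposite ends. Ms4a6c (179 against 0.714 CPM) and Ms4a6b (154 against 3.21 CPM) were also highest, and Msh5 (3.58 against 58.2 CPM) and H2-Q10 (3.07 against 55.0 CPM) lowest. In unnamed cluster 21 (44 and 45 cells) the class I median was 0.61 and the immediate early median -0.34, with 9 of 20 members lower and 3 higher. Fosb (1771 against 841 CPM, ratio 2.11, 1.63 to 2.73) and Fos (3029 against 1872 CPM, ratio 1.62, 1.35 to 1.94) were among the higher members there. How many cells of the cluster held these UMIs was not examined.

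**Figure D3:**
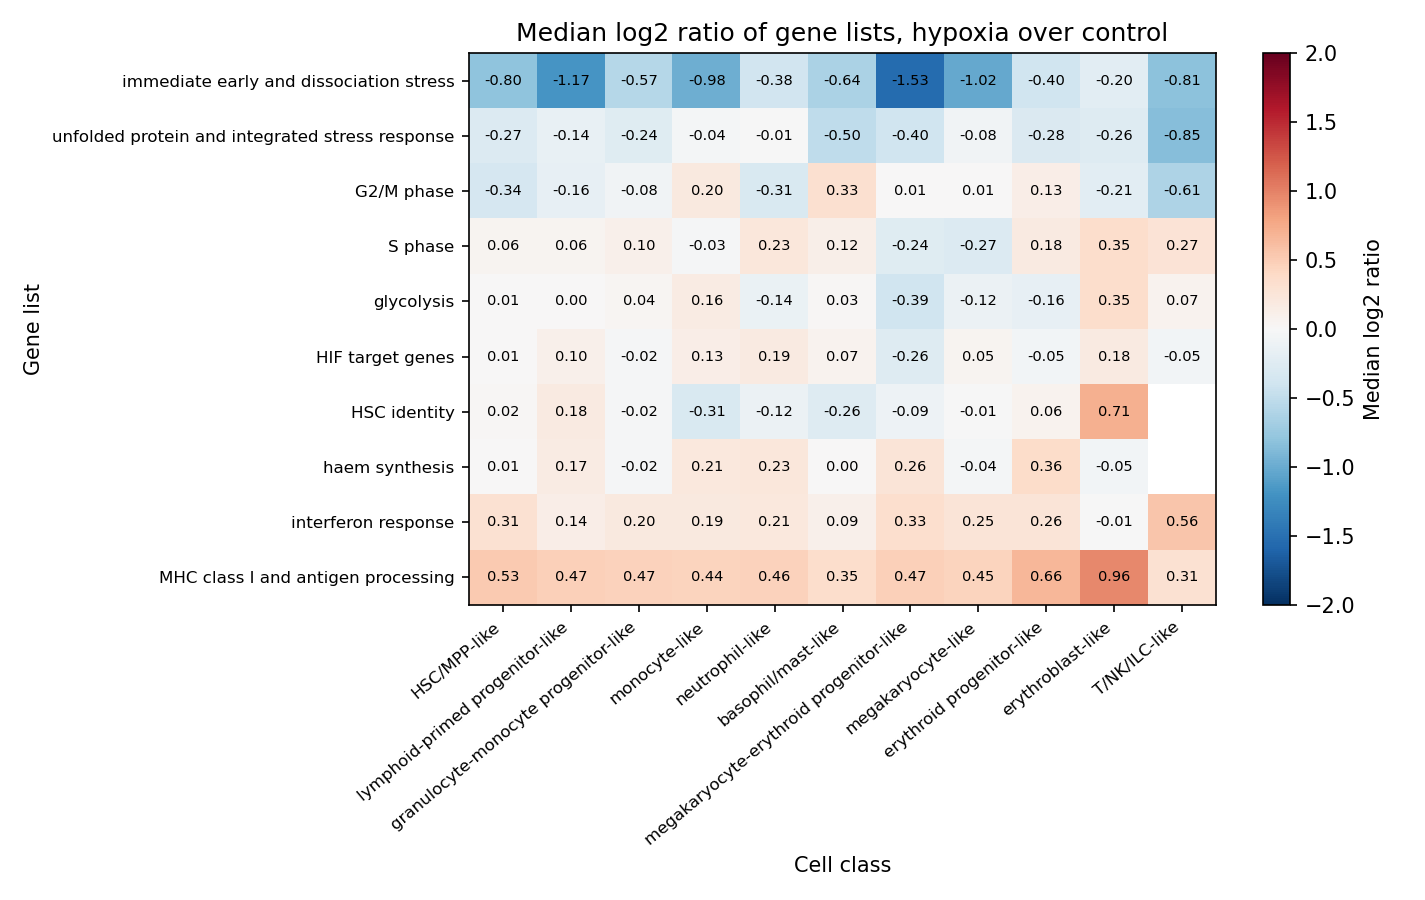
Median log2 ratio (hypoxia over control) of the measured members of 10 gene lists in 11 named classes (all-gene medians of 0.20 in erythroblast-like and 0.13 in neutrophil-like cells), with each value printed in its cell and blanks where a list had under 5 measured members. The immediate early and dissociation stress list runs from -1.53 to -0.20 (in erythroblast-like cells, and 0.10 there with no minimum of UMIs), and the class I list from 0.31 to 0.96.

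Over the whole libraries, which mix classes at different shares, Hba-a2 (131 against 6.07 CPM), Slc4a1 (160.3 against 36.8 CPM) and Tspo2 (139.8 against 32.9 CPM) of red-cell precursors, and Ms4a6c (98.1 against 11.6 CPM), Ccr2 (85.0 against 20.9 CPM), Ccl9 (209.6 against 56.1 CPM) and Ifi202b (54.3 against 11.7 CPM) of myeloid cells, were among the highest. So were Prg2 (469.7 against 131 CPM), Cpa3 (324 against 90.4 CPM) and H2-D1 (1169 against 271 CPM). The values of Ms4a6c and Ccl9 do not rest on the monocyte-like share alone. Ms4a6c was also higher within basophil/mast-like (UMIs in 408 of 670 and 2 of 313 cells), granulocyte-monocyte progenitor-like and HSC/MPP-like cells, and Ccl9 within granulocyte-monocyte progenitor-like cells. The lowest were Hsph1 (163 against 833 CPM), Cwc22 (54.7 against 217 CPM), Dnaja1 (307 against 803 CPM), Chordc1 (128 against 333 CPM), Hsp90aa1 (1801 against 4427 CPM), Glo1 (98.6 against 244 CPM), Hspa8 (849.6 against 1872 CPM), Rrs1 (48.2 against 113 CPM), Nrgn (56.5 against 128 CPM) and Hspa4l (102 against 221 CPM). The immediate early list had a median of -0.36 and the class I list 0.64, or 0.20 without the H2 region. HIF targets had a median of 0.012 and glycolysis -0.0041.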

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

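All tests in this part were chosen only after the result was seen, and what would count for or against handling and the cluster boundary was reworded after the first value of each was known. Cluster 28, which kept no name and entered no comparison, held 0.351% of hypoxia cells (22 cells) against 0.0255% of control cells (1 cell), and its leading genes included Cd3e, Trdc and Il7r.

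Across the 11 named classes compared, 7 genes were at least 1.5-fold higher and 12 at least 1.5-fold lower in the hypoxia library in every class where they were measured, among 10436 genes measured in 5 or more classes. That is with 10 CPM added. With 1 CPM added there were 28 higher and 32 lower genes, and with 50 CPM 2 and 4. Of the 19 genes found with 10 CPM added, the only setting examined here, 5 lay inside the H2 region of chromosome 17 (4 without the heat-shock gene Hspa1b), where random sets of measured genes reached at most 4, which is what a variant at that region carried by the animals of 1 library may give. The region was drawn around the H2 genes, and the set was already seen to hold H2-D1, H2-Q6 and H2-Q7. The count therefore largely restates what prompted it. H2-Q6 and H2-Q7, which may share reads, are not independent members. No other region was examined in this way. Ms4a4b, Ms4a4c, Ms4a6b and Ms4a6c, each among the highest genes of a class, lie within chromosome 19 from 11404770 to 11531256. A variant there was not tested. Nor was a variant tested at genes of the set outside the H2 region, such as Cwc22 on chromosome 2 and Glo1 on chromosome 17. Reads moved from 1 class I paralog to another would leave the summed family even, but its log2 ratio in HSC/MPP-like cells was 1.42 (1.37 to 1.47). Reads that were dropped or failed to align would not leave it even. How such reads were handled is not given in the sources used here, so that cause stays open. An interferon response may also contribute, since 40 class I pathway and interferon genes outside the region had a median of 0.27, above all random lists. These include the interferon response list, already reported above at percentile 100 in the same cells, so that outcome was known beforehand. Of the 40 genes 9 were at least 1.5-fold higher, 0 lower and 31 between. Some other genes of the region were lower in the hypoxia library. Msh5 was lower in 9 of 9 named classes where measured, with log2 ratios between -3.30 and -0.032. An H2-Q10 UMI was found in 0 of 120 hypoxia and 42 of 70 control neutrophil-like cells. The region therefore did not differ in 1 direction only. Class I genes are themselves interferon targets, so the variant, an interferon response and the chamber stay all stay open.

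Heat-shock and immediate early transcripts were lower in the hypoxia library, with a median log2 ratio of -0.80 for the immediate early and dissociation stress list in HSC/MPP-like cells. A difference in depth would predict a smaller gap in cells matched on UMIs, but with 189 matched cells per library (1 random draw) the median was -1.08. Sums were already scaled to the total of the class before matching, so matching was a weak test of depth. A small part of the control cells could not carry the Hsph1 difference, because the median control erythroid progenitor-like cell had 962 CPM and the hypoxia upper quartile was 274 CPM. The list median was below 0 in 11 of 11 named classes (in erythroblast-like cells its counting interval included 0, and it was 0.10 with no minimum of UMIs), but in unnamed cluster 21, at -0.34, 3 of 20 members were higher, among them Fosb with a ratio of 2.11 (1.63 to 2.73) and Fos with 1.62 (1.35 to 1.94). These intervals leave out variation between the few cells of that cluster. Time of collection, handling and the chamber stay could each give lower values over the named classes, and with 1 library per group these cannot be told apart.

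Late erythroid-like cells, taken as clusters 4, 14 and 29 after the data were seen, made up 13.1% of hypoxia and 4.34% of control cells, a ratio of 3.01 (2.55 to 3.57). Less complete removal of mature cells of every lineage would raise the neutrophil-like, B-lineage-like and T/NK/ILC-like cells as well, but together they had a ratio of 0.930 (0.736 to 1.18). Without the top 5% of doublet scores, which removed 9 of the 820 hypoxia cells, the ratio was 2.95. The placing of the cluster boundary may account for part of the erythroblast-like share, whose ratio went down to 0.624 and was below 1 in 3 of 12 other clusterings and namings, although classes by marker score gave 2.31 (1.98 to 2.69). The value of 0.624 rested on cluster 29 alone, with 8 cells in each library. Its shares of 0.127% (0.0550 to 0.251) and 0.204% (0.0883 to 0.402) had overlapping intervals. Monocyte-like (2.72, 2.34 to 3.19), eosinophil-like (2.08, 1.26 to 3.57) and basophil/mast-like cells (1.33, 1.17 to 1.53) also had larger shares in the hypoxia library. Together with the neutrophil-like, B-lineage-like and T/NK/ILC-like cells they had a ratio of 1.71 (1.57 to 1.87). Not all of these need be mature cells, since monocyte-like clusters 8 and 12 were also led by the progenitor markers Mpo and Prtn3. Less complete removal of some lineages, late erythroid cells among them, and the chamber stay were not tested and stay open.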

How the results depend on the processing

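The alternatives that left out H2-region genes, stress genes or a cluster, and those with other naming contrasts, were chosen only after the result was seen. Over the alternatives, 127 of 160 share ratios, 721 of 940 list medians, 1303 of 1782 log2 ratios of named genes, 14 of 60 shares of cells with a UMI and 4 of 8 counts of genes that differed in every class stayed within their counting interval (within 1.5 times for the counts). Direction turned, where the interval excluded no difference, in 5 share ratios, 4 list medians and 6 named genes. The immediate early medians of named classes stayed below 0 under every alternative run, except in erythroblast-like cells, where the median was 0.10 with no minimum of UMIs. A higher pseudocount shrinks, and a lower one widens, the log2 ratios of low genes by construction, and the other causes were not tested. Named below by class are all values that turned, and the values that moved beyond their interval among all share ratios and the list medians that lead each comparison, which were picked after values were seen.

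Centring genes within library gave share ratios of 0.831 (HSC/MPP), 7.73 (erythroblast), 0.768 (erythroid progenitor), 1.37 (granulocyte-monocyte progenitor), 1.87 (monocyte). Classes by marker score gave share ratios of 0.535 (HSC/MPP), 2.31 (erythroblast), 0.815 (erythroid progenitor), 0.523 (megakaryocyte-erythroid progenitor) and G2/M medians of -0.45 (HSC/MPP). The same setting gave interferon medians of 0.23 (HSC/MPP) and globins medians of 0.30 (erythroblast). The same setting gave class I medians of 0.35 (erythroblast), 0.73 (erythroid progenitor) and HIF target medians of -0.019 (erythroid progenitor). The same setting gave haem synthesis medians of 0.20 (erythroid progenitor) and immediate early medians of -0.35 (erythroid progenitor), -0.22 (neutrophil). The same setting gave log2 ratios of 0.52 (F13a1 in HSC/MPP), -0.067 (Kit in HSC/MPP), 0.049 (Vcam1 in monocyte). Naming against all other cells (chosen after the data were seen) gave share ratios of 0.553 (HSC/MPP), 3.01 (erythroblast), 1.24 (erythroid progenitor). Shares over progenitor classes alone gave share ratios of 0.833 (HSC/MPP), 1.04 (erythroid progenitor), 1.21 (granulocyte-monocyte progenitor). Clustering each library alone gave share ratios of 1.59 (T/NK/ILC), 0.847 (erythroblast). Use of no cell filter gave share ratios of 1.98 (erythroblast), 0.819 (erythroid progenitor). Thinning to 1000 UMIs gave share ratios of 0.702 (erythroblast), 0.769 (erythroid progenitor), 6.12 (monocyte). Naming against the mean of the other clusters (chosen after the data were seen) gave share ratios of 0.624 (erythroblast), 0.971 (erythroid progenitor), 3.83 (monocyte). Keeping doublets gave share ratios of 0.746 (erythroid progenitor), 1.24 (granulocyte-monocyte progenitor) and G2/M medians of -0.37 (HSC/MPP). The same setting gave haem synthesis medians of 0.15 (erythroid progenitor) and immediate early medians of -0.42 (erythroid progenitor), -0.52 (granulocyte-monocyte progenitor). Resolution 2 gave share ratios of 0.817 (erythroid progenitor). The stricter cell filter gave share ratios of 1.30 (granulocyte-monocyte progenitor) and lymphoid regulators medians of -0.061 (HSC/MPP), as well as G2/M medians of -0.37 (HSC/MPP) and globins medians of -1.46 (erythroblast), as well as immediate early medians of -0.52 (erythroid progenitor), -0.51 (granulocyte-monocyte progenitor) and log2 ratios of -0.24 (Car1 in HSC/MPP). Resolution 0.5 gave share ratios of 1.40 (granulocyte-monocyte progenitor), 1.94 (monocyte). Clustering without stress and H2-region genes (chosen after the data were seen) gave share ratios of 1.40 (granulocyte-monocyte progenitor), 2.24 (monocyte). TMM factors gave immediate early medians of -0.46 (whole library), -0.85 (HSC/MPP), -0.51 (erythroid progenitor) and class I medians of 0.55 (whole library), 0.59 (erythroid progenitor), as well as G2/M medians of -0.39 (HSC/MPP) and globins medians of -1.68 (erythroblast), as well as HIF target medians of -0.070 (erythroid progenitor) and haem synthesis medians of 0.24 (erythroid progenitor). Median-of-ratios factors gave immediate early medians of -0.45 (whole library), -0.85 (HSC/MPP), -0.46 (erythroid progenitor) and class I medians of 0.56 (whole library), as well as G2/M medians of -0.39 (HSC/MPP) and globins medians of -1.70 (erythroblast), as well as HIF target medians of -0.067 (erythroid progenitor) and haem synthesis medians of 0.29 (erythroid progenitor). The erythroid progenitor values of that setting rest on sums without scaling for depth. A pseudocount of 1 CPM gave immediate early medians of -0.43 (whole library), -0.84 (HSC/MPP), -0.62 (erythroid progenitor), -0.76 (granulocyte-monocyte progenitor), -1.16 (monocyte) and class I medians of 0.92 (whole library), 1.60 (erythroblast), 1.01 (erythroid progenitor), 0.63 (granulocyte-monocyte progenitor), as well as G2/M medians of -0.37 (HSC/MPP) and HIF target medians of -0.22 (erythroid progenitor). A pseudocount of 50 CPM gave immediate early medians of -0.21 (whole library), -0.53 (HSC/MPP), -0.14 (erythroid progenitor), -0.34 (granulocyte-monocyte progenitor), -0.61 (monocyte) and class I medians of 0.32 (whole library), 0.32 (HSC/MPP), 0.31 (erythroblast), 0.22 (erythroid progenitor), 0.22 (granulocyte-monocyte progenitor), 0.26 (monocyte), as well as G2/M medians of -0.22 (HSC/MPP) and interferon medians of 0.15 (HSC/MPP), as well as HIF target medians of -0.013 (erythroid progenitor) and haem synthesis medians of 0.22 (erythroid progenitor). Means of per-cell CPM gave immediate early medians of -0.48 (whole library), -0.49 (erythroid progenitor) and class I medians of 0.55 (whole library), as well as globins medians of -1.99 (erythroblast) and log2 ratios of -0.018 (Hlf in HSC/MPP). Means of list members gave class I medians of 0.72 (whole library), 0.85 (HSC/MPP), 0.69 (granulocyte-monocyte progenitor), 0.57 (monocyte) and globins medians of -0.91 (erythroblast), as well as HIF target medians of -0.11 (erythroid progenitor) and haem synthesis medians of 0.39 (erythroid progenitor), as well as immediate early medians of -0.46 (erythroid progenitor), -0.89 (monocyte). Leaving H2-region members out (chosen after the data were seen) gave class I medians of 0.20 (whole library), 0.10 (HSC/MPP), 0.39 (erythroblast), 0.14 (erythroid progenitor), -0.0034 (granulocyte-monocyte progenitor), -0.027 (megakaryocyte-erythroid progenitor), 0.24 (monocyte), 0.093 (neutrophil). Totals without globin, mitochondrial and ribosomal genes gave globins medians of -1.59 (erythroblast) and immediate early medians of -1.04 (monocyte). Leaving out cluster 29 (chosen after the data were seen) gave globins medians of -1.17 (erythroblast) and log2 ratios of 0.21 (Xpo7 in erythroblast). No minimum of UMIs gave globins medians of -0.54 (erythroblast) and class I medians of 0.39 (erythroblast). Leaving out cluster 4 (chosen after the data were seen) gave haem synthesis medians of 0.15 (erythroid progenitor) and immediate early medians of -0.34 (erythroid progenitor). Leaving out own markers gave haem synthesis medians of 0.31 (erythroid progenitor).

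With each library clustered alone, no share ratio could be formed for HSC/MPP-like, B-lineage-like, lymphoid-primed progenitor-like and megakaryocyte-erythroid progenitor-like cells. The lymphoid-primed name was also lost at resolution 0.5 and in thinned cells. The megakaryocyte-erythroid name was also lost with no filter, the stricter filter, the top 5% of doublet scores removed, resolution 0.5, thinning, clustering without stress and H2-region genes, and both other naming contrasts. TMM factors moved the median of all genes by -0.12 and median-of-ratios factors by -0.14 in erythroblast-like cells, both by -0.13 in neutrophil-like cells, and the latter by -0.16 in T/NK/ILC-like cells, where they left the sums unscaled. Counting error was widest where a class was small, as in the 35 control erythroblast-like cells.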

Other observations

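The genes and lists followed across classes in this part were chosen only after their values were seen. The unfolded protein and integrated stress response list had a median below 0 in 11 of 11 named classes, between -0.85 and -0.0094. Ccnd2, a D-type cyclin, was lower in the hypoxia library in 10 of 10 named classes where it was measured, and Pim1, a kinase that STAT5 can induce, in 11 of 11. Mitochondrially encoded genes had a median above 0 in 11 of 11 named classes, between 0.10 and 0.55. Per retained cell the median share of UMIs was 7.04% against 6.55% for mitochondrial genes and 12.8% against 14.3% for ribosomal protein genes. HIF targets had medians between -0.26 and 0.19, above 0 in 7 named classes and below 0 in 4. MHC class II medians were above 0 in 9 of 9 named classes with a measured member, between 0.041 and 1.36. The H2 members of that list, such as H2-Aa, lie inside the H2 region, while Cd74 lies on chromosome 18. The class II medians are therefore not separate from the differences in that region.

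The 7 genes that were higher in every named class where measured were H2-D1, H2-Q6, H2-Q7, Gdpd3 and the predicted or uncharacterised genes BC023719, Gm10320 and Gm47015. The 12 that were lower were the chaperone genes Hsph1, Hsp90aa1, Hspa8, Hspa4l, Hspa1b and Chordc1, and Cwc22, Glo1, Rrs1, Slc15a2, Zfp979 and Gm4631. These counts depended on the pseudocount, with 28 higher and 32 lower at 1 CPM and 2 higher and 4 lower at 50 CPM. The first included all 19 genes and the second was a subset of them.

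Cluster 21, also unnamed, held 0.701% of hypoxia and 1.15% of control cells, and its leading genes were Il7r, Gata3 and Id2. It is not among the classes counted above. There Ccnd2 was at 848 against 543 CPM, a ratio of 1.56 (1.12 to 2.20), opposite to the named classes, and Pim1 at 606 against 1040.1 CPM, a ratio of 0.582 (0.423 to 0.796). The median was 0.0087 for the unfolded protein list, 0.34 for HIF targets and 0.34 for mitochondrially encoded genes.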
